A study of Lathyrus oleraceus with 6 samples.

How the data were processed

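RNA of pea root nodules was sequenced as total RNA treated with DNase I, on a HiSeq instrument with single reads of 51 nt. The 6 libraries form 2 groups of 3, nodules with wild type bacteria and nodules with the dctA mutant that carries maeP, and each library holds nodules of 3 plants from 1 growth assembly at 25 days after inoculation. Per the submitters' notes the authors used FastQC, Bowtie2, HTSeq and DESeq2, with no versions. Genome build, annotation and read filters are not stated in the sources used here.

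Values used were those of the authors' deposited tables, 1 for bacterial genes and 1 for pea unigenes, as named by their headers. The baseMean column is a signal, per the file headers the mean over all libraries of counts divided by the authors' size factors. The log2 fold change and its standard error are log2 values in the deposited tables, shrunken towards 0. The stat column is a score in the deposited tables, the Wald statistic. The p-value columns hold, per the file headers, the authors' p-value and adjusted p-value. In the authors' values the statistic was the log2 fold change divided by its standard error, with a largest difference of 8.53e-14. The adjusted p matched a Benjamini-Hochberg adjustment over both organisms together, not within either, after a filter on mean count. Mean normalized counts of bacterial and plant genes share 1 scale, so bacterial fold changes are relative to all transcripts, most of them from pea.

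Count models planned for per-library counts were replaced by the deposited fold changes and p-values, because the tables hold no value per library. For the same reason the number of libraries showing a direction, a test of the bacterial share of counts, and paired or reshuffled comparisons could not be given. Size factors were recovered from rows whose mean normalized count matches 1 read in 1 library, on each side of the comparison. The side was read from dctA. Each library's approximate total is its size factor times the summed mean normalized counts, and equal normalized totals are assumed. No structural RNA was found among the annotations (0 rRNA or tRNA rows).

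A gene was called changed at an adjusted p under 0.05 in the authors' deposited tables, 29757 genes having an adjusted p. Intervals of single genes are 95% normal intervals of the authors' estimates. Those of the bacterial slope and of the photosynthesis difference came from resampled genes, and that of the plasmids from matched lists. Such intervals over sets treat genes as independent and do not measure spread between libraries. Gene lists, 19 bacterial and 20 plant, and the comparisons were fixed before the data were examined, as patterns on gene symbols and annotation text. Lists of at least 3 tested genes were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the authors' Wald statistics, at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of an organism. Random lists, 10000 per list, were matched on mean normalized count in 20 bins, and the smallest p they can give is 0.0001. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used otherwise. The procedure was tested on simulated Wald statistics of the same genes and lists, drawn as independent and without a trend with abundance. It therefore does not show how correlated genes or such a trend affect the list tests. At a simulated change of 4 standard errors, 59.6% of 198 changed genes were recovered, 4.72% of 127 called genes were unchanged, 4 of 4 shifted lists were recovered and 0 of 33 unshifted lists were called.

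Genes were named by rule: dctA, dctB, dctD and maeP, the 10 largest rises and 10 largest falls per organism among called genes, up to 4 members per list by smallest p, and nifH, nifD, nifK and nifA. The condition that the groups do not overlap could not be applied. Other genes, 11 of 106 bacterial and 12 of 95 plant genes named, were chosen after their values were seen. Alternatives were other adjustments, filters, thresholds and correlations, and matched lists. Annotation is the only basis of list membership.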

Results

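Root nodules of pea (Pisum sativum cv. Homesteader) were compared between plants inoculated with wild type Rhizobium leguminosarum bv. viciae and plants inoculated with a derivative that lacks a functional dctA and expresses maeP of Streptococcus gallolyticus. DctA is the transporter that takes up C4-dicarboxylates such as malate and succinate into the bacteria, and MaeP is a malate transporter. The comparison bears on how both partners express their genes when the nodule bacteria carry the foreign malate transporter in place of DctA. There were 6 libraries, 3 per strain, each made from total RNA of the nodules of 3 plants from 1 growth assembly, collected 25 days after inoculation. Bacterial and plant transcripts were counted from the same libraries.

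The tables hold 1 value per gene and comparison, by the authors, and no value per library. The authors' deposited table of bacterial genes has 7263 rows, of which 6018 carry an adjusted p-value, and that of plant genes has 45908 rows, of which 23739 do. Fold changes are the authors' shrunken log2 values, so the change of weakly counted genes is understated. Rows with a single read in 1 library give the size factors of the libraries, which were 0.884, 1.02 and 1.05 on one side of the comparison and 0.924, 0.973 and 1.22 on the other. With 1.76e+07 normalized counts per library on average, these correspond to about 1.56e+07 to 2.15e+07 counts per library if normalized totals were alike. Bacterial genes made up 18.2% of the mean normalized counts, a share that could not be given per library or tested. The headers do not name which strain is the numerator. The sign was read from dctA itself: the side on which dctA is lower was taken as the dctA mutant with maeP, and "lower" and "higher" below mean lower and higher in its nodules. With the opposite reading each direction turns round.

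To place the mutated gene first, the C4-dicarboxylate transport genes were examined. dctA (RL3424) stood at a log2 fold change of -1.87 (SE 0.10, adjusted p = 7.45e-73) in the authors' deposited table, 3.66-fold lower, at a mean normalized count of 3625. It cannot check the strain labels independently, because the direction was read from it. Next to it lie dctB and dctD, for the sensor kinase and response regulator of the same system. In the authors' deposited table dctB (RL3425) was higher, at 0.56 (SE 0.11, adjusted p = 0.000131), and dctD (RL3426) stood at 0.41 (SE 0.16, adjusted p = 0.176) and did not pass. Adjusted over the list alone, all 3 passed. No row is named maeP, and its expression was not analysed here. Of the 10 tested genes of TRAP and other dicarboxylate carriers, none passed, and 2 had an unadjusted p under 0.05. Those 2 were the TRAP transporter genes RL4358, at 0.30 (adjusted p = 0.293), and RL4359, at 0.38 (adjusted p = 0.376), in the authors' deposited table. There the dicarboxylate carrier gene matC (RL0992) stood at 0.32 (adjusted p = 0.535) and the binding protein gene dctP (RL2001) at -0.18 (adjusted p = 0.761).

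Among bacterial genes, 496 of 6018 passed an adjusted p of 0.05 in the authors' deposited table, 250 higher and 246 lower. On the authors' shrunken scale changes were mostly small, with a median size of a called change of 1.50-fold. On that scale 42 genes, 29 higher and 13 lower, changed at least 2-fold. Before shrinkage more would reach 2-fold, such as amtB (RL4564), at -0.78 log2 shrunken and approximately -1.03 before it. The strongest falls lay in 1 stretch of the chromosome that is annotated mostly with components of ABC transporters. The solute-binding protein gene RL0983 had -2.73 (SE 0.15, adjusted p = 1.41e-73) in the authors' deposited table, the lowest value of all bacterial genes. Its neighbours RL0982, RL0980, RL0981, RL0979 and RL0984 were at -2.37, -2.32, -2.05, -1.97 and -1.79 in the authors' deposited table, each past the threshold. RL0985, RL0986 and RL0987, singled out after their values were seen because they continue the stretch, were lower as well in the authors' deposited table, at -0.75, -0.61 and -0.61. The other genes among the 10 with the largest falls were dctA, the hypothetical genes pRL70054 (-1.81) and pRL70066 (-1.70), and acoD (RL4267), annotated as an acetaldehyde dehydrogenase, at -1.21 (SE 0.12, adjusted p = 2.42e-22) in the authors' deposited table.

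Among the 10 largest rises were hypothetical genes, transporter genes and a gene of tyrosine breakdown. RL1929 and the adjacent putative ATP-dependent hydrolase gene RL1930 both stood at 1.62 in the authors' deposited table, with adjusted p = 1.87e-21 and 4.18e-27. The hypothetical genes RL0931, RL2119 and RL4673 were at 1.53, 1.30 and 1.28 in the authors' deposited table, and RL4674, listed as a pseudogene, was at 1.29. Others were the transporter genes RL1489 of the MatE family and pRL110060 of the ABC type, both at 1.41 in the authors' deposited table, and RL2178, a putative cell division gene, at 1.32. RL1863, the gene of 4-hydroxyphenylpyruvate dioxygenase, an enzyme of tyrosine breakdown, had 1.43 (SE 0.13, adjusted p = 6.55e-25) in the authors' deposited table. Its neighbours hmgA (RL1864), the homogentisate dioxygenase gene of the same pathway, RL1865 and RL1866, named after their values were seen, were higher at 1.18, 0.93 and 0.93 in the authors' deposited table.

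**Figure D1:**
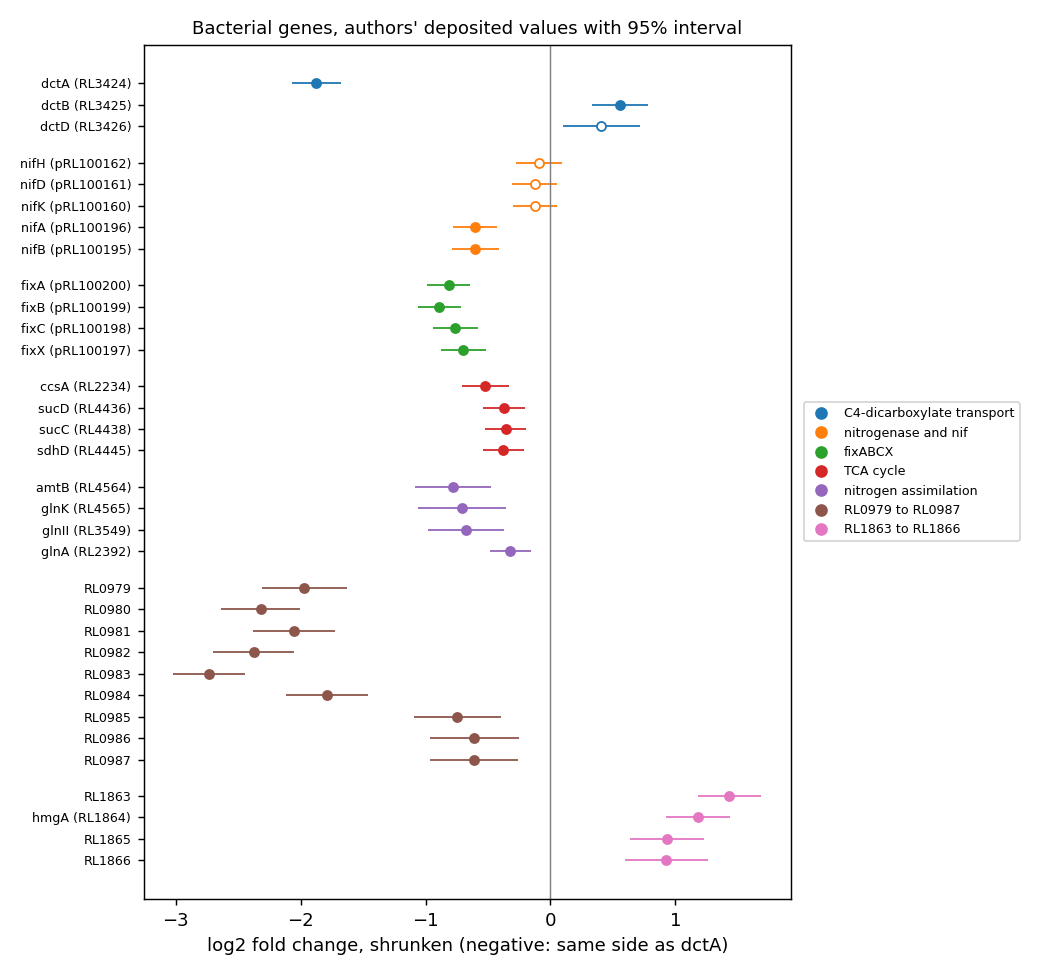
Log2 fold changes (horizontal axis, shrunken, authors' deposited values) of bacterial genes grouped by function or neighbourhood, with points as estimates, open where an adjusted p of 0.05 was not passed, and bars as the 95% interval. dctA lies at -1.87 while dctB lies at 0.56, nifH, nifD and nifK lie near 0, and fixA, fixB, fixC and fixX lie between -0.89 and -0.70.

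Among genes for nitrogen fixation, some passed and others did not. All 4 genes of the fixABCX list, whose products pass electrons to nitrogenase, were lower in the authors' deposited table: fixB (pRL100199) at -0.89 (SE 0.09, adjusted p = 1.55e-20), fixA (pRL100200) at -0.82, fixC (pRL100198) at -0.76 and fixX (pRL100197) at -0.70. In the list of nitrogenase and its regulators, 2 of 7 genes passed in the authors' deposited table, the regulator gene nifA (pRL100196) at -0.61 (SE 0.09, adjusted p = 5.58e-09) and the cofactor gene nifB (pRL100195) at -0.60 (adjusted p = 7.67e-08). The structural genes of nitrogenase did not pass: nifH (pRL100162) stood at -0.09, nifD (pRL100161) at -0.13 and nifK (pRL100160) at -0.12 in the authors' deposited table, with adjusted p = 0.877, 0.745 and 0.731. Their 95% intervals in the authors' deposited table, -0.28 to 0.10, -0.31 to 0.06 and -0.30 to 0.05, leave room for a small change either way. Of 23 tested genes for the microaerobic cbb3 oxidase and its regulators, 6 were lower and 1 higher, with fixQ1 (pRL100206A) at -0.49 (adjusted p = 5.00e-05), fixO1 (pRL100206) at -0.38 and fixP1 (pRL100207) at -0.39 against fixN3 (RL0536) at 0.63 (adjusted p = 0.00454) in the authors' deposited table. Adjusted over the list alone, 4 of 4 fixABCX genes, 2 of 7 nitrogenase genes and 19 of 23 oxidase genes passed, the latter 15 lower and 4 higher.

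Genes of the TCA cycle and of nitrogen assimilation were lower where they passed. In the TCA cycle list 12 of 19 genes were lower and none higher, 18 when adjusted over the list alone, and the largest change was that of the citrate synthase gene ccsA (RL2234), at -0.52 (SE 0.09, adjusted p = 7.09e-06) in the authors' deposited table. sdhD (RL4445) of succinate dehydrogenase and sucD (RL4436) and sucC (RL4438) of succinyl-CoA synthetase were at -0.38, -0.37 and -0.36 in the authors' deposited table. No gene of the 12 for malic enzyme and gluconeogenesis passed, and the malic enzyme gene dme (RL2671) stood at -0.19 (adjusted p = 0.297) in the authors' deposited table. Of 22 genes for nitrogen assimilation, 4 passed, all lower in the authors' deposited table, namely the ammonium transporter gene amtB (RL4564) at -0.78 (SE 0.16, adjusted p = 6.94e-05), the PII protein gene glnK (RL4565) at -0.71, and the glutamine synthetase genes glnII (RL3549) at -0.68 and glnA (RL2392) at -0.32. Of 31 genes for heat shock proteins and chaperones, 9 were lower and 2 higher, with clpB (RL4279) at -0.70 (adjusted p = 5.55e-11), ibpA (RL4089) at -0.58 and the chaperonin gene groLch1 (RL0883) at -0.59 against its paralogue groLch2 (RL1412) at 0.73 (adjusted p = 1.25e-05) in the authors' deposited table. groSch2 (RL1410), named after its values were seen, was higher too, at 0.85 in the authors' deposited table. In the NADH dehydrogenase list 1 of 19 genes passed, RL3214 at -1.18 (SE 0.12, adjusted p = 1.54e-18) in the authors' deposited table, and of the nuo genes nuoM (RL1713) stood at -0.31 without passing. Adjusted over the list alone, 1 malic enzyme and gluconeogenesis gene, 5 nitrogen assimilation genes, 17 heat shock genes and 3 NADH dehydrogenase genes passed.

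In other lists few genes passed. Of 54 ribosomal protein genes 4 were lower in the authors' deposited table, rplP (RL1781) at -0.44, rplD (RL1775) at -0.35, RL4549 at -0.35 and rpsI (RL1672) at -0.31. Of 11 ATP synthase genes and 14 amino acid transport genes of the aap and bra systems none passed, and of 79 motility and chemotaxis genes, which mark free-living bacteria, none did. These 3 lists without a call had 4, 0 and 6 genes at an unadjusted p under 0.05. Of all tested bacterial genes 23.8% had such a p, and counts adjusted over a list alone are to be read against this share too. Of 13 nodulation genes 2 were higher in the authors' deposited table, nodM (pRL100180) at 0.60 (SE 0.13, adjusted p = 0.000688) and nodN (pRL100179) at 0.69. Of 26 iron acquisition genes 2 were higher and 2 lower in the authors' deposited table, with the siderophore-interacting protein gene RL2916 at 0.66 (adjusted p = 0.000979) and vbsC (pRL120320) at 0.55, against the iron regulator gene rirA (RL0777) at -0.34 (adjusted p = 0.00296) and sitA (RL3884) at -0.32. In the lists for polyhydroxybutyrate and glycogen (11 genes), exopolysaccharide (43 genes) and cell division (20 genes), 1, 1 and 2 genes passed. They were pRL100105, a polyhydroxyalkanoate synthase subunit gene, at -0.51, pssJ (RL3648) at -0.36, hflB (RL3965), a membrane protease gene, at -0.46, and RL2178, in the authors' deposited table. Adjusted over the list alone, 17 ribosomal protein, 3 nodulation, 7 iron acquisition, 2 polyhydroxybutyrate and glycogen, 3 exopolysaccharide and 8 cell division genes passed. Without the low-count filter in the adjustment, rplD, pssJ, vbsC and RL0986 no longer passed, with adjusted p from 0.0502 to 0.0605.

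The gene lists were then tested as sets with limma's cameraPR on the authors' Wald statistics, at a preset correlation of 0.01 and adjusted over the 19 bacterial lists. By this test 10 lists passed, all towards lower values, led by fixABCX (median log2 fold change -0.79, cameraPR adjusted p = 1.31e-16) and the TCA cycle (median -0.34, cameraPR adjusted p = 1.52e-11). The others were ribosomal proteins, NADH dehydrogenase, nitrogenase and its regulators, heat shock, the cbb3 oxidase, dicarboxylate transport, ATP synthase and nitrogen assimilation, with cameraPR adjusted p from 4.39e-06 to 0.0334. The 9 lists that did not pass had cameraPR adjusted p from 0.0636 to 0.842. A correlation estimated from the libraries could not be had from these values. At a set correlation of 0.05, ATP synthase and nitrogen assimilation no longer passed (adjusted p = 0.0777 and 0.129), and at 0.1 the cbb3 oxidase and heat shock lists did not either (adjusted p = 0.0953 for both). For dicarboxylate transport the median (0.41) and the test differ in sign, while its mean (-0.30) has the sign of the test. The call of this list rests on dctA alone, the mutated gene from which the sign was read, and the other 2 genes had positive values, so it says nothing beyond dctA. For nodulation genes the median was -0.09 and the mean 0.02, with the cameraPR direction upward. Bacterial fold changes also depended on abundance. With the tested genes in 10 equal groups by mean count, the median log2 fold change went from 0.12 in the least counted to -0.21 in the most counted bacterial group, while the plant medians lay between -0.02 and 0.02. Against 10000 random lists matched on abundance, fixABCX alone stayed past the threshold (adjusted p = 0.0076), and the TCA cycle had an adjusted p of 0.286. The nitrogenase list did not pass against them (adjusted p = 0.861), and its median of -0.13 lay above the -0.23 of its matched lists. Its 2 called genes, nifA and nifB, lie in 1 run of neighbouring calls with fixABCX, so these lists are not independent. Random lists treat genes as independent, which genes of 1 operon are not.

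**Figure D2:**
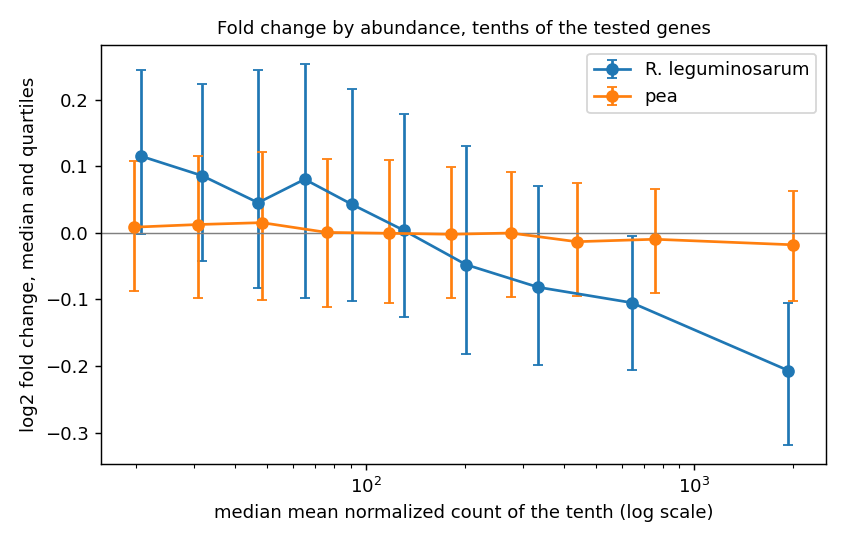
Log2 fold change (vertical axis) against the mean normalized count (horizontal axis, log scale) in 10 equal groups of the tested genes of each organism, with points as group medians and bars from the lower to the upper quartile of its genes. The bacterial medians run from 0.12 to -0.21, and the pea medians stay between -0.02 and 0.02.

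Among pea genes, 321 of 23739 passed an adjusted p of 0.05 in the authors' deposited table, 153 higher and 168 lower. On the shrunken scale, which understates changes, 24 of them changed at least 2-fold. Rows are unigenes, named here by the identifiers and annotations of the table. A sulfate transporter gene, PsCam020853, had the lowest value, -2.32 (SE 0.17, adjusted p = 2.96e-41) in the authors' deposited table. There were also 5 unigenes of the Bet v I family of pathogenesis-related proteins among the 10 largest falls, PsCam027683, PsCam005733, PsCam023981, PsCam002883 and PsCam007844, at -1.93, -1.92, -1.62, -1.61 and -1.54 in the authors' deposited table. How reads that match several similar unigenes were counted is not stated in the sources used here, so the values of these 5 cannot be taken as independent. The remaining 4 were PsCam059841 (-1.72) and PsCam038139 (-1.69), without annotation, PsCam038080, annotated as HI0933-like (-1.38), and the glutamine amidotransferase gene PsCam051637 (-1.29) in the authors' deposited table.

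The highest value was that of a chitinase gene, PsCam031133, at 1.43 (SE 0.18, adjusted p = 2.21e-12) in the authors' deposited table. Next came PsCam049923, annotated as solute carrier family 3 (amino acid transporters, activator), at 1.33 in the authors' deposited table. A cyclic nucleotide-gated channel gene, PsCam024759, followed at 1.25 in the authors' deposited table. PsCam052184, annotated as apolipoprotein D, and the serine carboxypeptidase-like gene PsCam035388 were at 1.23 and 1.22 in the authors' deposited table. The last of the 10 were PsCam044647 (1.19), an amino acid transporter gene PsCam043024 (1.15), a lipid-transfer protein gene PsCam002440 (1.06), an oligopeptide transporter gene PsCam036471 (1.03) and PsCam001752 (0.99) in the authors' deposited table.

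In the list for sugar and nitrogen transport, drawn from annotation text, 5 of 106 genes were higher and none lower, among them a cationic amino acid transporter gene, PsCam055911, at 0.67 (SE 0.12, adjusted p = 6.80e-06) and a sugar transport protein gene, PsCam045600, at 0.58 in the authors' deposited table. The others were PsCam049923, PsCam036471 and, named after its values were seen, the cationic amino acid transporter gene PsCam016752 at 0.38 in the authors' deposited table. By functional bin, chosen after the values were seen, called transporter genes of amino acids and sugars went both ways, with 4 higher and 3 lower of 115 for amino acids and 1 higher and 1 lower of 61 for sugars, while 2 were higher and 0 lower of 63 for peptides. Of 5 tested genes for organic acid and dicarboxylate transport, 1 passed, PsCam042553, annotated as a C4-dicarboxylate or malic acid transporter, at -0.55 (SE 0.14, adjusted p = 0.00813) in the authors' deposited table. No gene passed in the lists of nodulins (37 genes), ammonium assimilation (28 genes) and malate supply (31 genes), which had 4, 5 and 3 genes at an unadjusted p under 0.05. Of all tested plant genes 7.56% had such a p. The most counted glutamine synthetase unigene of those named, PsCam043042, stood at 0.18 (adjusted p = 0.425) and glutamate synthase PsCam006801 at -0.20 (adjusted p = 0.351) in the authors' deposited table. The named malate dehydrogenase unigenes went both ways there. PsCam023420 stood at -0.19 (adjusted p = 0.385), PsCam042882 at 0.44 (adjusted p = 0.0757) and PsCam033986 at 0.33 (adjusted p = 0.489). No annotation matched the lists of leghemoglobins and nodule cysteine-rich peptides, which were not analysed here.

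Photosynthesis genes, which mark green tissue, were higher: 10 of 64 tested passed, all higher, and 23 when adjusted over the list alone. Named members were the photosystem I subunit genes PsCam052133 at 0.57 (SE 0.11, adjusted p = 5.07e-05), PsCam043379 at 0.53, PsCam051442 at 0.45 and PsCam052823 at 0.43 in the authors' deposited table. In the list for ethylene, jasmonate and ABA 6 of 244 genes were higher and 16 lower, the latter all lipoxygenase unigenes, with an ACC oxidase gene of ethylene synthesis, PsCam044389, at 0.91 (SE 0.10, adjusted p = 2.04e-17) and lipoxygenase genes PsCam006625, PsCam020803 and PsCam016756 at -0.71, -0.69 and -0.58 in the authors' deposited table. The same lipoxygenases, which are assigned to the jasmonate bin and whose annotation text mentions senescence, also count in the list for senescence and proteolysis. In that list 5 of 106 genes were higher and 18 lower. Of these 18, 16 were lipoxygenases, and among the 73 members that are not lipoxygenases 4 were higher and 2 lower, with a median log2 fold change of 0.06. A cysteine proteinase gene of that list, PsCam011165, was at -0.63 (adjusted p = 1.20e-05) in the authors' deposited table. The 5 higher ones, named after their values were seen, were PsCam040950, a cysteine proteinase inhibitor gene, at 0.62, a lipoxygenase gene PsCam033261 at 0.54, PsCam028901 at 0.49, a legumain gene PsCam049954 at 0.48 and PsCam034756 at 0.38 in the authors' deposited table. Of 22 genes for iron and heme, 2 were higher and 1 lower in the authors' deposited table, a ferritin gene, PsCam050313, at 0.82 (SE 0.13, adjusted p = 6.97e-08), a metal-nicotianamine transporter gene, PsCam054071, at 0.63, and a vacuolar iron transporter gene, PsCam030926, at -0.33.

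Of 222 defense genes 4 were higher and 5 lower. The lower ones were the Bet v I genes above, and the higher ones were PsCam031133 and, named after their values were seen, a chitinase gene PsCam039684 at 0.90 and the WRKY transcription factor genes PsCam037669 at 0.62 and PsCam038186 at 0.43 in the authors' deposited table. Of 172 genes of the phenylpropanoid and flavonoid list 4 were lower, led by PsCam043094, annotated by its product naringenin-chalcone, at -1.19 (SE 0.17, adjusted p = 8.43e-10), with PsCam057756 at -0.66, an isoflavone reductase gene, PsCam057928, at -0.62 and PsCam037629 at -0.55 in the authors' deposited table. By functional bin, that of flavonoids had 0 higher and 4 lower of 97 genes (cameraPR adjusted p = 0.00502, and 0.242 at a correlation of 0.05) and that of phenylpropanoids 2 higher and 0 lower of 96 (adjusted p = 0.891), a difference that was not tested. In the cell division list, of which 114 of 165 tested genes are annotated as histones, 5 genes passed, all lower and all histone genes. They were the H2A genes PsCam044608 at -0.37, PsCam007365 at -0.34 and PsCam007555 at -0.34, the H3 gene PsCam052485 at -0.29 and, named after its values were seen, the H1 gene PsCam025681 at -0.27 in the authors' deposited table. None of 209 ribosomal protein genes, 65 genes for water stress and 77 for lignin and suberin passed, with 33, 9 and 7 at an unadjusted p under 0.05. In the lists for heat shock proteins (137 genes), oxidative stress (134 genes) and the root cell wall (49 genes), 1 higher and 2 lower, 2 higher and 4 lower, and 1 lower gene passed. They were the heat shock genes PsCam024416 at 0.39, PsCam042606 at -0.32 and PsCam045359 at -0.42, and a proline-rich protein gene of the cell wall list, PsCam044612, at -0.37 in the authors' deposited table. Of the oxidative stress list, PsCam055850 was at 0.45, PsCam044688 at -0.67, PsCam040159 at -0.53 and a protein disulfide isomerase gene PsCam042411 at -0.30 in the authors' deposited table. A thioredoxin gene PsCam000244 at 0.55 and a protein disulfide isomerase gene PsCam017148 at -0.28, also from the authors' deposited table, were named after their values were seen. Adjusted over the list alone, 11 sugar and nitrogen transport, 2 organic acid transport, 27 hormone, 33 senescence, 5 iron and heme, 9 defense, 4 phenylpropanoid, 7 cell division, 6 oxidative stress, 1 cell wall and 0 heat shock genes passed, the last with 15 at an unadjusted p under 0.05. With the adjustment within plant genes alone, PsCam007365, PsCam052485, PsCam025681, PsCam042606, PsCam045359, PsCam017148, PsCam037669, PsCam040950 and PsCam049954 no longer passed, with adjusted p from 0.0513 to 0.0896.

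Tested as sets with limma's cameraPR over 18 plant lists, 8 passed, 2 towards higher and 6 towards lower values. Photosynthesis was higher (median log2 fold change 0.18, cameraPR adjusted p = 8.08e-16), as was iron and heme (median 0.06, adjusted p = 0.0202). Lower were cell division (median -0.14, adjusted p = 9.52e-11), ribosomal proteins (median -0.13, adjusted p = 5.12e-10), phenylpropanoid and flavonoid, water stress, senescence and proteolysis, and malate supply, with cameraPR adjusted p from 0.000495 to 0.0269. The 10 other lists had cameraPR adjusted p from 0.0712 to 0.941. Medians and means differed in sign for ammonium assimilation (0.01 and -0.01, direction upward) and defense (0.00261 and -0.04, direction downward), and for nodulins (-0.00157 and 0.000842, direction downward). The call of cell division did not extend to the functional bins of the cell cycle (106 genes, median -0.05, cameraPR adjusted p = 0.296) and of cell division (98 genes, median 0.00673, adjusted p = 0.606), and the median of the list's 51 members other than histones was -0.07. The call of senescence and proteolysis came with a median of -0.00169 and did not hold on ranks (adjusted p = 0.972), nor did that of iron and heme (adjusted p = 0.33). In the protein degradation bin 9 of 1131 genes were higher and 4 lower, with the cameraPR direction upward (adjusted p = 0.628). At a set correlation of 0.05 only photosynthesis, cell division and ribosomal proteins passed, and the other 5 had an adjusted p of 0.123 (iron and heme, phenylpropanoid, water stress), 0.18 (malate supply) and 0.261 (senescence). At 0.1 only photosynthesis passed (adjusted p = 0.00127).

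**Figure D3:**
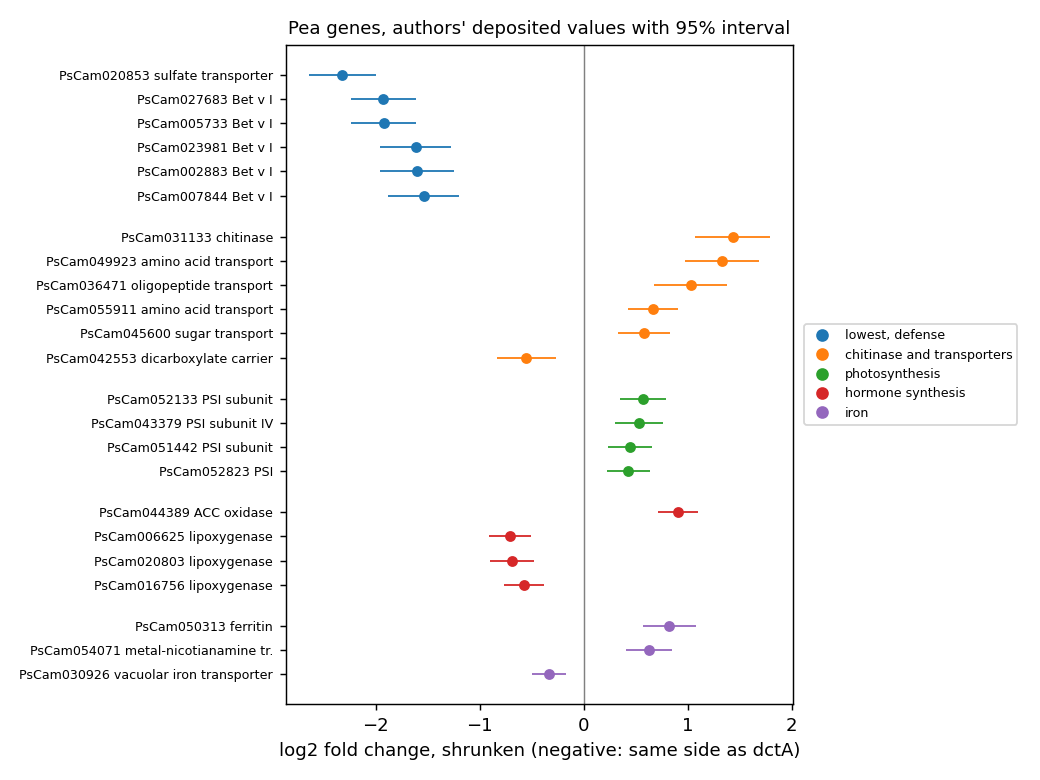
Log2 fold changes (horizontal axis, shrunken, authors' deposited values) of named pea unigenes, with points as estimates and bars as their 95% interval. The sulfate transporter gene lies at -2.32 and the 5 Bet v I genes between -1.93 and -1.54, while photosystem I genes lie between 0.43 and 0.57.

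**Figure D4:**
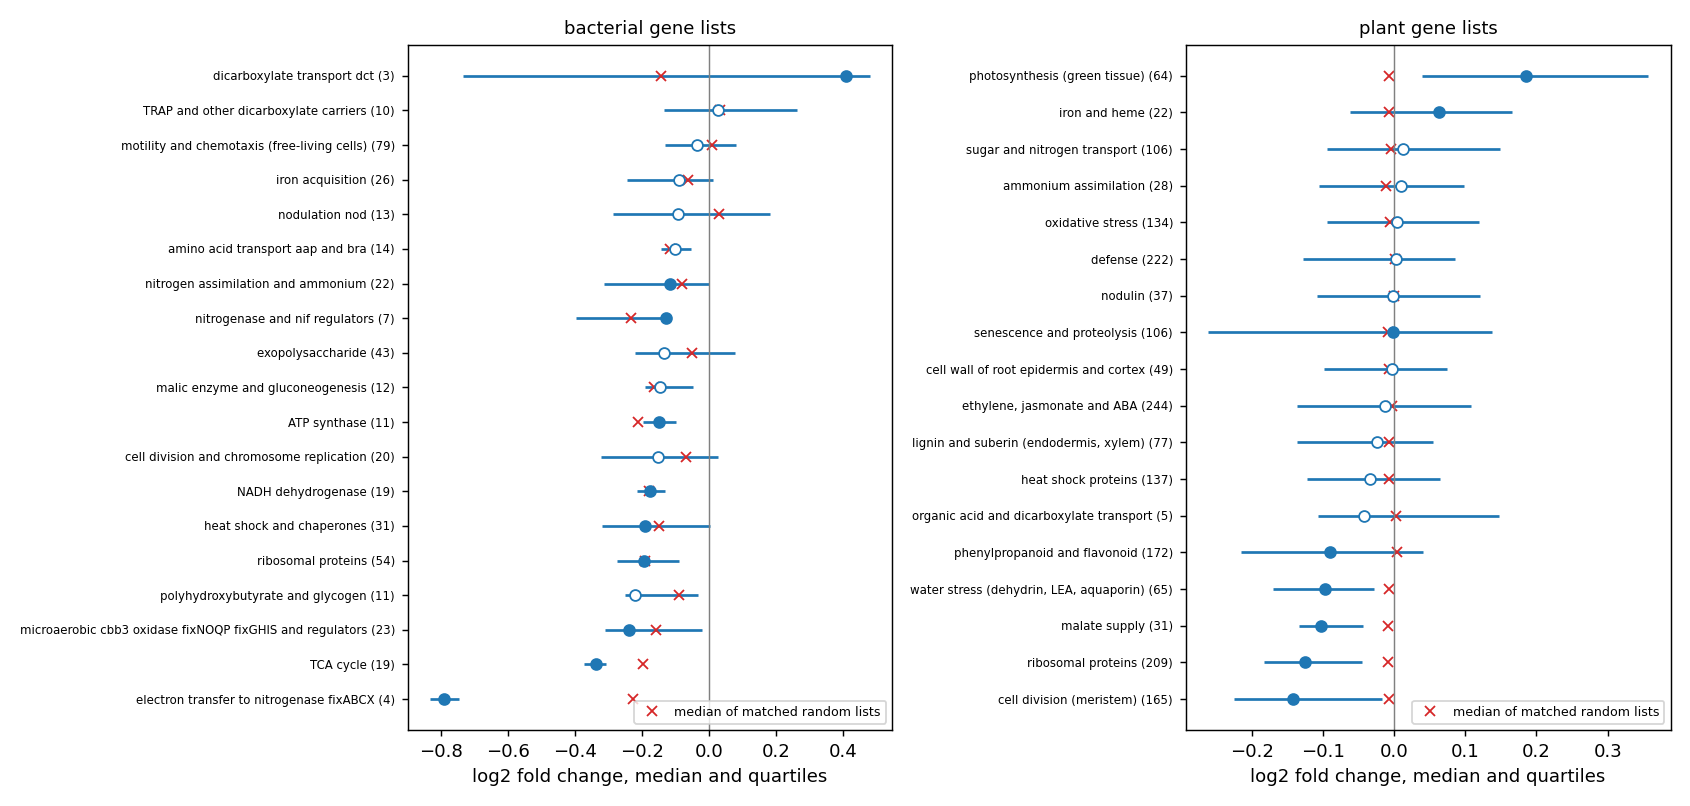
Median log2 fold change (horizontal axis) of the tested genes of each list, with bars from the lower to the upper quartile, points filled where cameraPR at a preset correlation of 0.01 passed, crosses at the median of random lists matched on abundance, and numbers giving the genes tested. The fixABCX median of -0.79 lies far below its matched lists, whereas bacterial ribosomal proteins lie on theirs.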

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

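All alternatives below except the fold threshold, the adjustment without a low-count filter for the counts of genes, and the share without the most abundant genes were chosen after the data were seen. At a shrunken change of at least 2-fold, 42 bacterial and 24 plant genes were called. At an adjusted p under 0.01, 197 plant and 337 bacterial genes were called. Both counts are smaller by the construction of these thresholds. Without the low-count filter 443 bacterial genes (442 of them among the 496) and 280 plant genes (278 among the 321) were called, and with the adjustment within each organism 734 and 253. With a mean normalized count of at least 100, 409 bacterial and 306 plant genes were called, and 36.2% of the bacterial calls were higher, against 50.4%.

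Bacterial lists past the test numbered 10, and 6 at a correlation of 0.1 and 1 against matched lists. Of the plant lists, 8 passed, and 3 at a correlation of 0.05 and 1 at 0.1, since a larger correlation widens the test, with 6 on ranks and 10 against matched lists, which added defense (adjusted p = 0.0088) and sugar and nitrogen transport (adjusted p = 0.00669). Against matched lists the bacterial lists for malic enzyme and gluconeogenesis (0.589), amino acid transport (0.406), ribosomal proteins (0.301) and ATP synthase (0.788) reversed, and so did nodulation (-0.182), values being mean Wald statistics minus those of matched lists. None of these reversed values passed against matched lists (adjusted p from 0.633 to 0.811). On ranks, as mean percentile minus 50, dicarboxylate transport (13.9), nodulation (-3.40) and plant ammonium assimilation (-0.105) reversed. None passed by cameraPR on ranks (adjusted p = 0.485, 0.717 and 0.986). In dicarboxylate transport only dctA had a negative value, and the cause of the other reversals was not tested. dctA stood at -1.87, and at approximately -2.04 before shrinkage. The latter is not an authors' value: it assumes a normal prior whose width was set from the largest standard error. Of 105 other named bacterial genes, 12 passed newly with the adjustment within the organism and 4 no longer passed without the low-count filter. Of 95 named plant genes 9 and 7 no longer passed. The bacterial share was 18.3% without the 10 most abundant genes of each organism, against 18.2%, and depth limits mainly genes of low count, where shrinkage is strongest.

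No paired analysis was possible because the tables hold no value per library. Not run for the same reason were the voom, RLE and upper-quartile fits, the stricter filter on counts within single libraries (unlike the minimum of the mean over all libraries above), pseudocounts, the replicate block, leaving out libraries, fry and an estimated correlation, and the exact test of the share. Leaving out structural RNA changed nothing, as there was none.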

Other observations

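The tests of runs, functional bins and explanations here were all chosen after the results were seen. Bacterial calls came in neighbouring groups: 29 runs of at least 3 adjacent tested genes were called the same way, 11 higher and 18 lower, with 123 genes, where 1000 shuffles of the calls gave at most 5 runs and a median of 1. These shuffles treat genes as independent, which genes of 1 operon are not, so the excess may reflect no more than shared operons. Runs of 10 genes were RL4430 to RL4439, with citM, sucA, sucD, sucC and mdh (median log2 fold change -0.34), and pRL100192 to pRL100201, with nifB, nifA and fixABCX (median -0.60). A run of 7 genes with pdhA, pdhB and pdhC of pyruvate dehydrogenase had a median of -0.40, and one with sufS1, sufD and sufC of iron-sulfur cluster assembly had -0.34. Higher runs included RL4672 to RL4675 (median 1.25) and RL3889 to RL3891 (median 1.14). Near dctA, RL3420 and RL3421 stood at 0.77 and 1.06 in the authors' deposited table.

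Among 132 functional bins of pea genes, 6 were higher and 18 lower by cameraPR at a correlation of 0.01, 3 passed at 0.05 and 2 at 0.1, and 29 against matched lists, which treat genes as independent. The jasmonate bin had 1 gene higher and 16 lower of 54 (median -0.19, cameraPR adjusted p = 2.42e-16, and 0.00201 at a correlation of 0.1). All 16 were lipoxygenase unigenes, whose reads are not independent if shared, and the 21 other genes of the bin had a median of -0.12. The bin of photosynthetic light reactions had 12 higher and 0 lower of 100 (median 0.16, adjusted p = 2.78e-16, and 0.0136). Sulphate transport, with 2 of 15 genes lower, passed at 0.01 (adjusted p = 0.00502) and against matched lists (adjusted p = 0.0178), not at 0.05 (adjusted p = 0.111) or on ranks (adjusted p = 0.645).

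Abundant bacterial transcripts were lower and rare ones higher, with a slope of -0.165 log2 per 10-fold mean count (95% interval -0.174 to -0.155). This interval came from resampled genes taken as independent and does not measure spread between libraries. A technical trend in all genes of a library is argued against as the whole cause by the plant slope of -0.0132. A smaller share of nitrogen-fixing bacteroids stays open: the mean of nifHDK lay above the median of the most counted group of genes by 0.0933 (SE 0.0924, taken as 1 gene), a difference whose 95% interval includes 0, and fixABCX, at -0.79 against -0.11 for nifHDK, belongs to the pattern itself. Reads from bacterial DNA or another even background stay open too: the median of 79 motility genes, -0.04 against 0.01 in matched lists, lay at percentile 6.65 of these. The strain difference itself stays open and untested, so the trend may be biological or technical.

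Calls on the plasmids pRL11 and pRL12 were nearly all higher, 62 against 5 lower, of 451 tested genes on pRL11 and 550 on pRL12. Lower abundance of plasmid genes, together with the choice of these 2 among 7 replicons, stays open. Matched lists of other genes held a median of 38 genes called higher (95% of lists 28 to 48). They held a median of 13 called lower (95% of lists 7 to 20), so the 5 seen lay under that range. Matched lists treat genes as independent. An excess of genes called higher as large, over some pair of replicons, came up in a share of 0.0627 of 10000 shuffles of blocks of 10 neighbouring genes. Calls lower were not shuffled in this way. More copies of both plasmids would raise all of their genes. Their median exceeded that of matched lists by 0.0314 log2 on the shrunken scale (95% interval 0.0203 to 0.0463, too narrow because neighbouring genes are not independent). That scale understates changes of weakly counted genes, and median counts were 65.4 on pRL11 and 49.4 on pRL12. Within this limit, the small difference argues against more copies as the whole cause. The strain difference, including any undescribed difference between the strains, may underlie the pattern and was not tested.

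Photosynthesis genes were higher, and green shoot tissue in the nodule samples is a candidate explanation. Chlorophyll a/b-binding genes, among the most abundant leaf transcripts, had a median of 0.08 over 21 genes with 0 called. The other 43 genes had a median of 0.27 with 10 called, a difference of -0.195 (95% interval -0.325 to -0.0776). That interval came from resampled genes taken as independent, which similar unigenes may not be, and does not measure spread between libraries. The most counted chlorophyll a/b-binding gene had a mean of 2466. The smaller rise of the chlorophyll a/b-binding genes cannot decide on green tissue, which stays open. A rise from such tissue would also depend on a gene's level in the nodules themselves, and the sets were not matched on count. The 10 called genes that define the pattern also all lie among the other 43. A change of the photosynthesis genes in the nodules stays open and untested. Whether other groupings of the 6 libraries call as many genes could not be counted without values per library, and 3 against 3 libraries allow only 10 splits.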
